A study of Mus musculus with 6 samples.

How the data were processed

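Messenger RNA from mouse retina was sequenced in 6 libraries, 3 from animals with a conditional knockout (CKO) of Cyfip2 and 3 from wild-type (WT) controls. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq stranded mRNA kit. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.3.5.1, SAMtools 1.11, Cufflinks 2.2.1 and the mouse build mm10, without stating the role of each. The gene annotation, the parameters and the use of strand are not given in the sources used here.

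The deposited values are in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), the unit that the named tool Cufflinks gives, with 1 value per gene symbol for 24346 symbols. The unit was also judged from the values, which are fractional and sum to between 402832 and 436299 per library. The median log2 deviation from the mean of all libraries lay between -0.0007 and 0.0026, so the libraries were already on a common scale; the step that set it is not given in the sources used here. In WT 3, 27 symbols had been turned into dates, and they were restored from the same row of the other libraries, whose symbols matched row by row. Of the symbols, 23310 (95.7%) were found in GENCODE M21 on GRCm38, which gave the positions printed here.

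FPKM keeps no read counts, so the absolute depth is unknown. Ratios between libraries at genes with a mean below 0.3 FPKM fell on ratios of small whole numbers in 69.2% to 74% of cases, within 0.02 on the log2 scale, and gave the depth relative to WT 1. It was 1.05 for CKO 1, 1.3 for CKO 2, 1.18 for CKO 3, 1.09 for WT 2 and 1.06 for WT 3. No interval for counting error could be set for single values, and the precision of each value was taken from the spread between libraries.

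Values were transformed to log2(FPKM + 1), and the 13215 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with no covariate and with Benjamini-Hochberg adjustment at 0.05. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. Adjusted p-values below come from this fit unless another test is named. With 3 against 3 libraries, a permutation test of a single gene cannot go below p = 0.1 (two-sided), so none was used.

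A set of 51 gene lists, covering retinal cell types, neighbouring eye tissues, actin regulation, synapse, ion channels, metabolism and stress, was fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but the removal of length and GC trends and of Ndufs5 from its list. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 47 lists that had at least 4 tested members. The camera variance trend was not part of that plan: a first run without it gave 11 lists, and it was then switched on to match the gene test, which gave 9. Not tested were 4 lists: 2 of 15 genes of cornea and conjunctiva, 3 of 17 of skeletal muscle and 3 of 14 of optic nerve oligodendrocytes passed the filter, and no symbol of the 26 of the mitochondrial genome was found. Cyfip2 was in none of the lists.

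The named genes are Cyfip2; the tested members of the WAVE regulatory complex list; in each direction up to 12 genes past the threshold whose groups did not overlap, ranked by fold change and filled up to 10 with the non-overlapping genes of smallest p, said to be short of the threshold; and the 4 members of smallest p from each list past its test. Predicted genes were otherwise only counted, and a few genes that the rule selects are not reported here. Genes named outside this rule, such as the further list members called adjusted over the list alone and the genes around Dkk3, were chosen after their values were seen.

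The alternatives were pseudocounts of 0.1 and 0.01, no filter or a minimum mean of 0.1 or 5 FPKM, rescaling by median-of-ratios size factors, quantile normalization, the replicate number as a block, robust eBayes, sample weights, eBayes without the trend, each library left out in turn, and 3 other list tests (camera with an estimated correlation, camera on ranks, and fry). A count-based test was not applied, since the values are not counts. Transcript length and GC came from the longest GENCODE M21 transcript of each symbol.

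The fit was tested on simulated data with noise drawn at each gene's moderated SD, in 10 simulations of 13215 genes with 200 changed. For CKO against WT it recovered 10.6% of genes changed by 0.25 (log2), 66% at 0.5, 95.4% at 1 and 99.4% at 2, with a mean of 7.6 unchanged genes called. A list shifted by 0.15 was called in 10 of 10 simulations, with a mean of 0.1 other lists called. Noise was drawn independently for each gene, so false calls of lists with correlated members were not simulated. In the data this correlation was estimated at 0.107 for oxidative phosphorylation and 0.67 for the lens list. Smaller shifts, such as the amacrine list mean of 0.086, and data with fewer than 200 changed genes were not simulated either.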

Results

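Retinal transcriptomes of Cyfip2 CKO mice were compared with those of WT controls to ask which transcripts differ when Cyfip2 is deficient in the retina. Cyfip2 encodes a subunit of the WAVE regulatory complex, which controls branched actin assembly. The Cyfip2 protein itself also contacts the fragile X protein FMRP. The data comprised 3 CKO and 3 WT libraries of retinal mRNA, with expression as FPKM per gene. Between 13149 and 13242 genes reached 1 FPKM in each library, and Pearson's r between libraries over the tested genes was 0.9681 to 0.9794. The 10 most abundant features took 9.66% of the summed FPKM in WT 3 and 5.65% to 6.27% in the others; in WT 3 the microRNA precursor Mir8104 was listed at 19268.5 FPKM. Xist was at 0.024 to 0.069 FPKM and the Y-linked Ddx3y at 17.3 to 19.7 FPKM in all 6 libraries. The labels do not state whether the samples of a group came from separate animals, and p-values then measure only the spread between these samples, which may be technical.

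Cyfip2 was 5.41-fold lower in CKO than in WT retina. Its level was 9.91 ± 1.45 FPKM in CKO and 53.6 ± 15.7 FPKM in WT (SD, n = 3 each), so that CKO libraries held 18.5% of the WT mean. The CKO libraries 1 to 3 were at 8.33, 10.2 and 11.2 FPKM, and the WT libraries 1 to 3 at 35.5, 63.1 and 62.3 FPKM. WT 1 was thus at 56.5% of the mean of the other WT libraries and still above every CKO library. The CKO mean was 27.9% of the level in WT 1 and 15.8% of the mean of WT 2 and WT 3. The labels give the genotype of WT 1 as wild-type with no detail of its alleles, and the fold of 5.41 includes this library as labelled. The log2 fold change was -2.29 (SE 0.21, 95% confidence interval -2.78 to -1.79, limma adjusted p = 0.02389). Cyfip2 lies on chromosome 11 from 46193850 to 46312859 on the minus strand (GRCm38), and a value per gene does not show from which exons the remaining signal came. The adjusted p rose above 0.05 when CKO 1 (0.1093), CKO 2 (0.1117), CKO 3 (0.1166), WT 2 (0.1973) or WT 3 (0.0663) was left out, as well as without the filter on low values (0.07396), with robust eBayes (0.1109) and without the variance trend (0.1024). The fold change stayed between -2.55 and -2.15 over all 18 alternative fits, and without WT 1 the adjusted p was 0.001597.

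**Figure D1:**
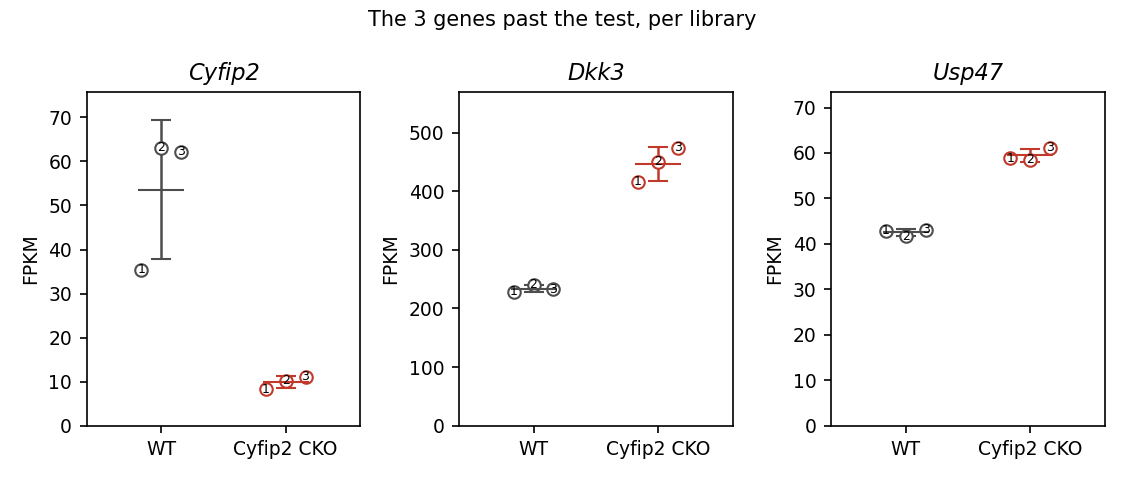
FPKM (vertical axis) of Cyfip2, Dkk3 and Usp47 in WT (grey) and CKO (red) retina; each circle is a library with its replicate number, and the long bar and whiskers give the mean ± SD of 3 libraries. For each gene the CKO libraries lie apart from the WT libraries, at 8.33 to 11.2 against 35.5 to 63.1 FPKM for Cyfip2.

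Besides Cyfip2, 2 genes differed past the threshold, and both were higher in CKO: Dkk3, which encodes a secreted glycoprotein of the Dickkopf family, and Usp47, which encodes a deubiquitinase. Dkk3 was at 446.9 ± 29.2 FPKM in CKO and 233.9 ± 6.15 FPKM in WT (SD, n = 3 each), a ratio of 1.91. Usp47 was at 59.5 ± 1.47 FPKM in CKO and 42.6 ± 0.777 FPKM in WT, a ratio of 1.40. Log2 fold changes were 0.93 (SE 0.06, limma adjusted p = 0.002744) for Dkk3 and 0.47 (SE 0.04, limma adjusted p = 0.02389) for Usp47. The genes are neighbours on chromosome 7 of GRCm38. Usp47 spans 112023504 to 112111661 on the plus strand and Dkk3 spans 112116017 to 112159057 on the minus strand, with 4355 bp between them. The 7 other tested genes within 1 Mb of the pair, among them Galnt18, Mical2, Parva and Tead1, had log2 fold changes of -0.08 to 0.17 (median 0.058), and none passed the threshold. Dkk3 stayed past the threshold in all 18 alternative fits. Among other fits, Usp47 was lost without the variance trend (adjusted p = 0.1511) and without CKO 1 (0.08602), CKO 2 (0.1117), CKO 3 (0.1166), WT 1 (0.1186), WT 2 (0.1973) or WT 3 (0.05789), while its log2 fold change stayed between 0.4538 and 0.4888 in all 18.

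**Figure D2:**
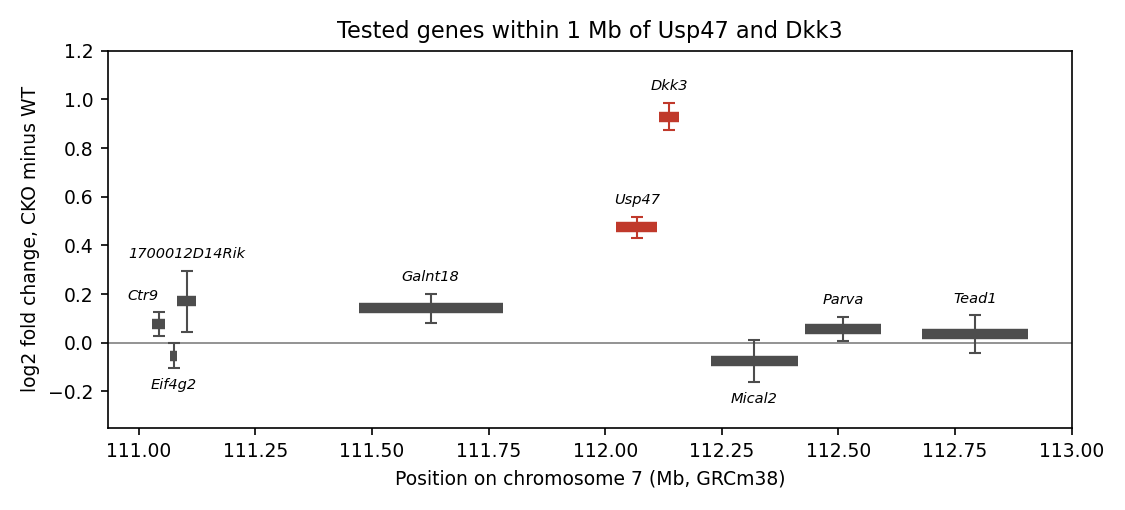
Log2 fold change, CKO minus WT (vertical axis), of the tested genes within 1 Mb of Usp47 and Dkk3 against position on chromosome 7 in Mb (horizontal axis, GRCm38); each bar spans a gene and whiskers give ± 1 SE. Dkk3 (0.93) and Usp47 (0.47) stand above their neighbours, which lie between -0.08 and 0.17.

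Over all 13215 genes tested, 2 were higher and 1 was lower in CKO by limma. At an unadjusted p under 0.05 there were 1041 genes, 465 higher and 576 lower, where 661 would be expected by chance. Splits of the 6 libraries that mixed CKO and WT gave 318 to 1311 such genes. The excess over 661 thus does not by itself show an effect of genotype. The CKO and WT groups did not overlap for 1838 genes (13.9%, against 10% by chance). When a library was left out, the count of higher genes was 1 without WT 1 and without WT 2, and the count of lower genes was 0 without CKO 2, CKO 3 or WT 2. The 1 lower gene was Pcsk1n without CKO 1 (adjusted p = 0.0201) and the microRNA gene Mir8113 without WT 3 (7.374e-07), in place of Cyfip2.

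Transcripts of the other subunits of the WAVE complex and its close relatives showed no difference past the threshold, and protein levels were not measured. Of 10 tested genes, 2 had fold changes above 0 and 8 below 0, with a mean log2 fold change of -0.045 (camera adjusted p = 0.5031, and 0.7661 with an estimated correlation). No member had an unadjusted p under 0.05, and none was called over all genes or adjusted over the list alone. Cyfip1, the paralog of Cyfip2, was at 7.33 ± 0.306 FPKM in CKO and 7.78 ± 0.193 FPKM in WT (SD, n = 3 each), a log2 fold change of -0.08 with a 95% confidence interval of -0.24 to 0.09. Nckap1, the Cyfip partner in the complex, was at 50.9 and 53.3 FPKM (-0.06, interval -0.17 to 0.04). Log2 fold changes of the genes for the WAVE proteins were -0.05 for Wasf1, 0.10 for Wasf2 and -0.0025 for Wasf3. Those of the Abi subunits were -0.0041 for Abi1, 0.02 for Abi2 and -0.24 for Abi3 (interval -0.55 to 0.06). Brk1 lay at -0.03 and Nckap1l, the blood cell form of Nckap1, at -0.10. The signs of Brk1, Wasf3 and Abi1 turned in some alternative fits.

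Among genes higher in CKO but short of the threshold, the smallest p belonged to Pla2g4e, a cytosolic phospholipase A2, at 4.73 ± 0.173 FPKM in CKO and 1.90 ± 0.304 FPKM in WT (SD, n = 3 each; log2 fold change 0.99, limma adjusted p = 0.06106). It passed with robust eBayes (0.04009) and with sample weights (0.02899). Slc1a2, a high-affinity glutamate transporter, was at 57.8 against 46.2 FPKM (0.32, adjusted p = 0.142), and Tac2, the neurokinin B precursor, at 22.9 against 13.7 FPKM (0.69, adjusted p = 0.1621). Tfap2b, a transcription factor of amacrine cells, was at 72.8 against 60.9 FPKM (0.25, adjusted p = 0.196). The antisense transcript 9430065F17Rik was at 4.72 against 2.04 FPKM (0.92, adjusted p = 0.196); how strand was used in counting is not stated. AI593442 was at 17.6 against 13.04 FPKM (0.40, adjusted p = 0.1585). Mir546, a short microRNA gene for which FPKM is unstable, was at 740.9 ± 204.9 against 237.3 ± 20.1 FPKM (1.603, adjusted p = 0.06694). It passed with quantile normalization (0.03799) and without CKO 2 (0.009459).

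Genes lower in CKO but short of the threshold included Vgf, a secreted neuropeptide precursor, at 5.77 ± 0.858 FPKM in CKO and 11.1 ± 0.907 FPKM in WT (SD, n = 3 each; log2 fold change -0.84, limma adjusted p = 0.1177). Prr7, a postsynaptic membrane protein, was at 4.33 against 6.99 FPKM (-0.58, adjusted p = 0.1177). Adnp, a chromatin regulator mutated in a neurodevelopmental syndrome, was at 6.78 against 11.3 FPKM (-0.65, adjusted p = 0.1585). Gng4, a G protein gamma subunit, was at 11.6 against 16.1 FPKM (-0.44), and Ehd4, an endocytic ATPase, at 12.6 against 19.5 FPKM (-0.60), both with adjusted p = 0.1585. Mfap4, an extracellular matrix glycoprotein, was at 0.973 against 3.80 FPKM (-1.26, adjusted p = 0.1585). H2afx, the histone H2AX gene, was at 14.7 against 20.5 FPKM (-0.45, adjusted p = 0.1365), and Tpgs1, a subunit of the tubulin polyglutamylase complex, at 21.7 against 29.5 FPKM (-0.43, adjusted p = 0.142). Cox5b, a subunit of cytochrome c oxidase, was at 231.8 against 281.4 FPKM (-0.28, adjusted p = 0.1585).

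Among 47 tested gene lists, 9 passed the camera test at the preset correlation, 3 higher and 6 lower in CKO. None of the 9 passed with the correlation between genes estimated from the data, a test that also uses fewer degrees of freedom, and the only list past fry, which tests each list by itself, was that of horizontal cells (adjusted p = 0.04923). No member of the 9 lists was called over all genes. Without WT 1 the number of lists past camera was 15.

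The amacrine cell list, markers of the inhibitory interneurons of the inner retina, was higher in CKO, and the horizontal cell list, markers of the inhibitory interneurons of the outer retina, was lower. Of 22 amacrine genes, 16 had fold changes above 0 and 6 below 0 (mean log2 fold change 0.086, camera adjusted p = 3.418e-05). With an estimated correlation the adjusted p was 0.1971. Adjusted over the list alone, 11 amacrine genes were higher. They included Tfap2b (72.8 ± 2.08 FPKM in CKO, 60.9 ± 0.127 FPKM in WT; SD, n = 3 each), the GABA-synthesizing enzyme Gad1 (122.3 ± 1.53 against 109.5 ± 2.56 FPKM) and C1ql2 (43.8 ± 4.93 against 33.7 ± 1.31 FPKM). Gad2, Meis2, Pax6, Slc17a8, Slc32a1, Tfap2a and Tfap2c were also among them. Prdm13 and Slc18a3 were lower adjusted over the list alone; Slc18a3 encodes the vesicular acetylcholine transporter of starburst amacrine cells. Of 14 horizontal cell genes, 1 had a fold change above 0 and 13 below 0 (mean -0.16, camera adjusted p = 1.701e-05). The adjusted p with an estimated correlation was 0.1971. Adjusted over the list alone, 6 were lower: Calb1, Gja10, Megf11, Vim, Adra2a and Ndrg1. Not all markers fell alike: Onecut1 was the gene above 0 (0.22), Onecut2 (-0.059) and Prox1 (-0.0051) lay near 0, and Onecut3 was at -0.22. Calb1, the calcium buffer calbindin, was at 26.6 ± 0.401 FPKM in CKO and 33.8 ± 3.09 FPKM in WT. Gja10, a connexin of horizontal cell gap junctions, was at 2.32 ± 0.179 against 3.36 ± 0.605 FPKM, and the adhesion receptor Megf11 at 8.24 ± 0.61 against 9.84 ± 0.268 FPKM. Vim, an intermediate filament gene also expressed in Muller glia, was at 110.8 ± 6.56 against 128.6 ± 10.3 FPKM. Of the tested members, 3 amacrine and 4 horizontal cell genes also stood in other lists.

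The retinal ganglion cell list, markers of the output neurons of the retina, was lower in CKO, with 7 genes above 0 and 21 below 0 among 28 tested (mean log2 fold change -0.095, camera adjusted p = 3.62e-05). With an estimated correlation the adjusted p was 0.2467. Adjusted over the list alone, 5 genes were lower: the neurofilament genes Nefl, Nefm and Nefh, the nicotinic receptor subunit Chrna6 and Nrn1. Nefl was at 221.1 ± 11.8 FPKM in CKO and 266 ± 19.9 FPKM in WT (SD, n = 3 each), Nefm at 66.1 ± 1.06 against 81.6 ± 5.24 FPKM, and Nefh at 36.1 ± 0.602 against 42.7 ± 1.94 FPKM. Chrna6 was at 37.8 ± 1.29 against 46.0 ± 0.631 FPKM. Of the 28 genes, 10 also stood in other lists. The list of ganglion cell subtypes, with 25 tested genes, did not pass (camera adjusted p = 0.7666); its mean was 0.0027 and its median -0.014, and the test pointed to lower.

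The cone photoreceptor list was lower in CKO, with 3 genes above 0 and 13 below 0 among 16 tested (mean log2 fold change -0.091, camera adjusted p = 0.002122). With an estimated correlation the adjusted p was 0.5684. Adjusted over the list alone, 3 genes were lower: the cone opsins Opn1mw (80.1 ± 4.52 FPKM in CKO, 101.8 ± 12.04 FPKM in WT; SD, n = 3 each) and Opn1sw (101.7 ± 7.56 against 121.9 ± 5.02 FPKM), and the potassium channel subunit Kcne2 (37.0 ± 0.643 against 45.0 ± 3.08 FPKM). Gulo lay in the other direction, at 10.8 ± 1.22 against 8.10 ± 1.40 FPKM. Of the 16 cone genes, 11 also stood in other lists. The cone bipolar list, markers of interneurons that carry cone signals, was lower too, with 4 genes above 0 and 15 below 0 among 19 tested (mean -0.086, camera adjusted p = 0.02602; adjusted p = 0.5684 with an estimated correlation). None of its genes was called adjusted over the list alone. Among its smallest p values were those of Cck (4.52 against 7.16 FPKM), Scgn (50.4 against 56.0 FPKM) and Glra1 (7.48 against 8.34 FPKM). This list did not pass without CKO 1 (adjusted p = 0.05255), CKO 2 (0.08202) or WT 2 (0.1941, with a mean of -0.056). The rod photoreceptor list (mean -0.048, adjusted p = 0.1293), the phototransduction list (mean -0.048, adjusted p = 0.06634) and the rod bipolar list (mean -0.0094, adjusted p = 0.7028) did not pass. The rod list passed without WT 1 (mean -0.081, adjusted p = 0.01882), and the phototransduction list without WT 1 (mean -0.085, 0.0004671) or CKO 3 (0.04771), with sample weights (0.02239) and after removal of length and GC trends (0.02956). Of the 41 phototransduction genes, 24 also stood in other lists. The smallest p values among them were those of Opn1sw, Opn1mw, Pde6c and Gnat2, all members of the cone list.

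The oxidative phosphorylation list was lower in CKO, with 16 genes above 0 and 59 below 0 among 75 tested (mean log2 fold change -0.038, median -0.05, camera adjusted p = 1.701e-05). With an estimated correlation the adjusted p was 0.5684. Ndufs5, named after its values were seen, had a fold change of 2.04 (SE 1.23), with 0.0177 FPKM in WT 3 and 30.8 to 45.8 FPKM in the other libraries. It moved the list mean: the other 74 genes had a mean of -0.0656 (camera adjusted p = 1.07e-05), a value added after the data were seen. With Ndufs5 the mean was -0.0151 with a pseudocount of 0.01, -0.0187 with quantile normalization and -0.0144 after removal of length and GC trends, and without it -0.0661, -0.0454 and -0.0425. Cox5b (231.8 ± 6.11 FPKM in CKO, 281.4 ± 5.34 FPKM in WT; SD, n = 3 each) and Ndufb2, a complex I subunit (73.1 ± 2.65 against 98.3 ± 11.9 FPKM), were lower adjusted over the list alone. Cox6a1 was at 287.2 ± 13.5 against 349.5 ± 28.1 FPKM and Cox5a at 134.3 ± 5.83 against 154.7 ± 5.91 FPKM.

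The list named dendrite and ciliary cytoskeleton was higher in CKO, with 21 genes above 0 and 7 below 0 among 28 tested. Its mean log2 fold change was 0.055 (camera adjusted p = 0.002122, and 0.5485 with an estimated correlation). The tested members are tubulin, stathmin, kinesin, dynein, ankyrin, spectrin and microtubule-binding genes. The list therefore does not measure cilia, or dendrites as opposed to axons. Stmn4, a tubulin-binding stathmin, was higher adjusted over the list alone, at 35.8 ± 1.41 FPKM in CKO and 28.1 ± 2.05 FPKM in WT (SD, n = 3 each). The kinesin motors Kif5c (68.1 against 62.5 FPKM) and Kif5a (74.1 against 68.6 FPKM) and the microtubule-associated protein tau gene Mapt (68.5 against 63.0 FPKM) did not pass by themselves. The list of glutamate receptors and their scaffolds was higher, with 34 genes above 0 and 15 below 0 among 49 tested (mean 0.029, camera adjusted p = 0.02602; adjusted p = 0.5684 with an estimated correlation). None of its genes was called adjusted over the list alone. Among its smallest p values were those of the AMPA receptor subunits Gria4 (44.6 against 40.0 FPKM) and Gria3 (20.2 against 17.8 FPKM) and of the kainate receptor subunit Grik2 (8.70 against 7.39 FPKM). The glutamate list did not pass without CKO 2 (mean 0.033, adjusted p = 0.05831), CKO 3 (0.0309, 0.05726), WT 1 (0.0258, 0.1087) or WT 3 (0.0135, 0.1826), with sample weights (0.0203, 0.06171) or after removal of length and GC trends (0.0243, 0.05906). Its mean was 0.048 without WT 2 and 0.05 with a minimum mean of 5 FPKM.

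The lens and crystallin list, markers of a neighbouring eye tissue, was lower in CKO with the mean furthest from 0 among the 9 lists, with 1 gene above 0 and 17 below 0 among 18 tested (mean log2 fold change -0.79, camera adjusted p = 4.438e-05). With an estimated correlation the adjusted p was 0.7661. None of its genes was called adjusted over the list alone. Cryaa, the lens chaperone alpha A crystallin, was at 102.8 FPKM in WT 2, 35.1 in WT 3 and 16.6 in WT 1, and at 9.22 to 20.5 FPKM in CKO. Cryba1 was at 55.8 FPKM in WT 2 and 4.98 to 18.5 FPKM in the other libraries, Crybb1 at 23.1 against 3.06 to 7.66 FPKM, and Crygs at 20.1 against 2.66 to 9.96 FPKM. Without WT 2 the list mean was -0.30 and the adjusted p was 0.06919, and without WT 1 they were -1.22 and 3.687e-11.

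**Figure D3:**
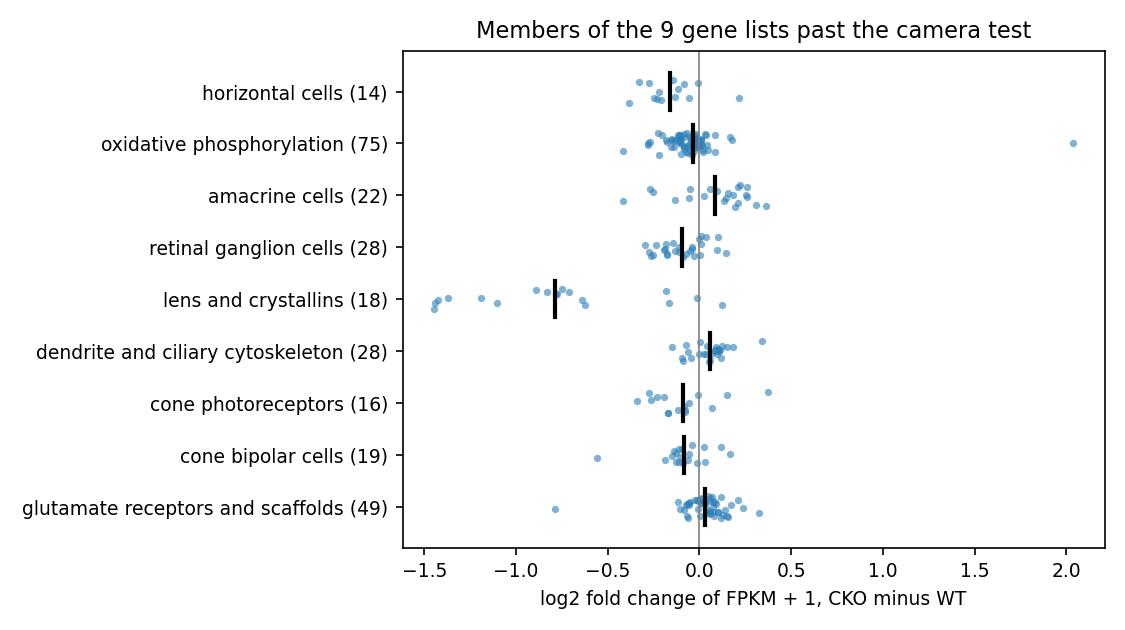
Log2 fold change, CKO minus WT (horizontal axis), of the tested members of the 9 lists past camera, with the number of members in brackets; each point is a gene and the black bar is the list mean. Members of the lens list reach furthest below 0, other lists have means between -0.16 and 0.086, and the point near 2 is Ndufs5.

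The other 38 lists did not pass, with camera adjusted p from 0.05683 to 0.9632 and mean log2 fold changes of -0.17 to 0.10. Astrocytes were at -0.17 (adjusted p = 0.05683) and passed in 7 of the 18 alternative fits (0.01764 to 0.04883), among them those without WT 1 or CKO 1, and on ranks. GABA and glycine receptors were at -0.083 (0.06169) and passed without WT 3 (0.01399). Axon guidance genes were at 0.041 (0.06169) and passed without WT 1 (0.04401), with a minimum mean of 5 FPKM (0.04415) and without the variance trend (0.04038). Genes of gliosis and retinal injury had a mean of -0.13 (0.1161) and passed without CKO 1 (mean -0.22, 0.03106), WT 1 (-0.28, 0.003065) or WT 2 (-0.21, 0.03522). They did not pass without CKO 2, CKO 3 or WT 3, the library where their member Gfap was highest (36.2 FPKM). The correlation between them was estimated at 0.58, far above the preset 0.01, and with it the camera adjusted p was 0.873. Genes of microglia and macrophages had a mean of -0.053 (0.6879). Ribosomal protein genes (mean -0.0078, 0.7028) passed as lower without WT 1 (mean -0.059, 0.04401) and as higher without WT 3 (mean 0.053, 0.005853). Retinal pigment epithelium genes (mean 0.10, 0.5993) passed without WT 1 (mean 0.22, 0.03947), and progenitor and cell cycle genes (mean -0.12, 0.1344) without WT 3 (0.03712). Muller glia were at 0.024 (0.6879), with Dkk3 as the member called over all genes. Genes of the Arp2/3 complex and other actin nucleators had a mean of -0.0082 (0.6879). FMRP partners and translational control genes had a mean of 0.0054 (0.7103), and synaptic vesicle genes a mean of 0.0063 (0.8485). Voltage-gated sodium and potassium channels had a mean of 0.0069 and a median of -0.013 (0.7103). The genes flanking Cyfip2 on chromosome 11 had a mean of -0.008 and a median of 0.012 (0.9632).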

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

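The removal of trends with transcript length and GC and of Ndufs5 from its list were chosen after the data were seen; all other alternatives were planned. Over 18 alternative fits, Dkk3 kept its direction and call in all (log2 fold change 0.89 to 0.98, adjusted p 0.0004356 to 0.04721). Cyfip2 and Usp47 kept their direction in all and their call in 10 of 18 each, with adjusted p up to 0.1973. The count of genes higher in CKO was 2; it was 3 without the filter, with quantile normalization, robust eBayes and sample weights, and 1 with the replicate block and with eBayes without the trend; with libraries left out it ranged from 1 to 3. The count of genes lower was 1, and 0 without the filter, with robust eBayes and without the trend, where Cyfip2 stayed at -2.29 with adjusted p of 0.07396, 0.1109 and 0.1024; without the filter 18580 genes entered the adjustment, and the cause was not tested otherwise. With libraries left out the count of lower genes ranged from 0 to 1 and the Cyfip2 fold change from -2.5546 to -2.1469, with fewer samples in each fit. The other features called there were Pcsk1n and Mir8113, which were the lower genes without CKO 1 and without WT 3 in place of Cyfip2, and the small RNA genes Mir3473g, Mir6992, Mir546, Mir703, Snora64 and Snora74a. The number of lists past camera was 9; it was 10 with a minimum mean of 5, quantile normalization, sample weights, ranks and removal of length and GC trends, 11 without the variance trend, 0 with an estimated correlation and 1 with fry, and ranged from 7 to 15 with libraries left out. The lists of horizontal, amacrine, ganglion and cone cells, oxidative phosphorylation and dendrite cytoskeleton passed in all 18 refits; the oxidative phosphorylation mean of -0.0375 was -0.0243 and -0.0151 with pseudocounts of 0.1 and 0.01, -0.0187 with quantile normalization and -0.0144 without length and GC trends, and without Ndufs5 -0.0656 in the main fit and -0.0661, -0.0661, -0.0454 and -0.0425 in these. With the block the rod (adjusted p = 0.04612), phototransduction (0.03513) and astrocyte (0.04883) lists were added. By fry for change in either direction, 20 lists passed. Signs near 0 turned for Wasf3 (0.017 with quantile normalization; -0.0265 to 0.0192 with libraries left out), Abi1 (0.0018 with quantile normalization, 0.0107 with sample weights, 0.0131 without length and GC trends; -0.075 to 0.0689) and Brk1 (-0.0633 to 0.0093); the cause was not tested. Of the other values for named genes, 1105 were on the same side of the threshold, 4 passed it and 8 fell short. The replicate numbers share no stated origin: same-numbered CKO and WT libraries deviated together with r of 0.0718, 0.0063 and 0.101, and not each correlated best with its own number; with the replicate block 2 genes (Cyfip2 and Dkk3; Usp47 at adjusted p = 0.09871) and 12 lists passed, 9 of them shared. No scaling moved the median of all genes by over 0.1. A test on read counts was not run, since the values are FPKM, and depth limits what can be said of single low values.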

Other observations

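The tests of the chromosome 7 pair, of rods, of lens tissue and of neighbouring pairs and the removal of length and GC trends were chosen only after the data were seen, and the genes of this and the next paragraph were picked after their values were seen. Neuropeptide genes lay in both directions between CKO and WT retina, and their list did not pass camera (22 tested genes, 11 above 0 and 11 below 0, adjusted p = 0.7555). Adjusted over the list alone, Tac2 was higher (log2 fold change 0.69), while Vgf (-0.84), Pcsk1n (-0.77) and Pdyn (-0.33) were lower. Pcsk1n, the proSAAS precursor, was at 28.1 ± 8.60 FPKM in CKO and 47.2 ± 3.86 FPKM in WT (SD, n = 3 each), and Pdyn, the dynorphin precursor, at 5.29 ± 0.342 against 6.93 ± 0.701 FPKM. None of these genes passed over all genes with the 6 libraries; Pcsk1n passed without CKO 1 (log2 fold change -0.997, adjusted p = 0.0201).

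In some other lists that did not pass camera, single genes were called adjusted over the list alone. Syt7, a calcium sensor of asynchronous release, was higher adjusted over the synaptic vesicle list alone (35.03 ± 1.66 FPKM in CKO, 28.2 ± 1.21 FPKM in WT; SD, n = 3 each). The T-type calcium channel gene Cacna1h was lower adjusted over its list alone (34.5 ± 2.23 against 42.1 ± 0.434 FPKM), and in the list of acetylcholine, dopamine and other transmitter receptors (10 genes above 0 and 13 below 0, mean -0.048, adjusted p = 0.4164) so were Chrna6 and the dopamine receptor gene Drd4, which is expressed in photoreceptors (95.8 ± 8.01 against 122.6 ± 8.30 FPKM). Over all genes the limma adjusted p of Syt7, Cacna1h and Drd4 were 0.2685, 0.2905 and 0.3044. Gfap, the glial filament gene, was at 36.2 FPKM in WT 3 and 20.2 FPKM in CKO 1, and at 9.94 to 11.04 FPKM in the other libraries. Mir8104 was listed at 19268.5 FPKM in WT 3 and 2059.1 FPKM in CKO 1, and at 0 in the rest.

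The joint rise of Dkk3 and Usp47 was weighed first. More Muller glia, which express Dkk3, are argued against by the other 19 markers of these cells, whose median log2 fold change was -0.0002 (SD 0.1251). Chance neighbours stay open: a pair of random tested genes is adjacent with a probability of 0.000157, but this holds for any pair and was computed after these genes were seen to be adjacent. Extra copies of a short chromosome 7 segment in the CKO animals stay open too, since Cre lines made from a large genomic clone around Dkk3 are in use for deletion in retinal progenitors; the labels name no Cre line, and the copy number was not measured. The 7 flanking genes had a median of 0.0576, which is also expected if Dkk3 and Usp47 respond to Cyfip2 loss, so it does not favour extra copies. Such a response and a strain difference linked to this locus stay open, untested.

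The opposite directions of the amacrine list and of the horizontal, ganglion cell and cone lists were weighed next. A trend with transcript length or GC as the whole cause is argued against, since 4 of the 4 lists passed after its removal; across genes, which are not independent replicates, Spearman's rho of the fold change was 0.137 with length and 0.0182 with GC. A changed share of rods alone would move both interneuron lists alike. The difference between their means, amacrine minus horizontal, was 0.42 to 0.45 in CKO and 0.17 to 0.21 in WT libraries, apart by 0.2447. These lists were compared because they had passed in opposite directions, so this gap restates the pattern and is no independent test. The share of rods itself was not measured, and it may have changed along with other causes. A change of cell composition or of expression within these cells with the Cyfip2 genotype may underlie the pattern and stays open. Correlation between genes, estimated at 0.026 for ganglion cells and 0.155 for cones, also stays open for these lists; for horizontal and amacrine cells it was estimated at 0.0027 and 0.0075, below the preset 0.01, so a higher correlation did not end their calls in that test.

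The lower lens and crystallin list may come in part from lens tissue carried into the library WT 2. WT 2 was singled out by its crystallins, so the smaller list mean without it (-0.2983) does not test this. The median log2 deviation over the 18 tested genes of the list, most but not all of them crystallins, was 1.57 in WT 2 and -1.01 to 0.18 in the others. Of the 8 lens genes in the list that are not crystallins, 6 were highest in WT 2, where 1.33 would be expected by chance, but their median level of 0.787 FPKM is too low to decide. Of the 18 tested genes, 2 also stand in other lists, and retina itself expresses several crystallins; a genotype effect on these stays open, untested.

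Other splits of the 6 libraries into 3 and 3 were fitted in the same way. As many as the real 3 genes were called in 3 of 10 splits, the real one included, and the highest other count was 4, with CKO 1, CKO 2 and WT 1 against the rest, where 1311 genes had an unadjusted p under 0.05. As many as the real 9 lists were called in 2 of 10 splits, and the highest other count was 9. With 10 splits the share cannot fall under 0.05. Single lists were compared over the splits only for the 9 that passed in the real split. That choice favours low p-values in the real split, so the comparison does not test these lists. The camera p of the real split and the lowest of the others were 4.554e-07 and 0.02085 for horizontal cells, 2.181e-06 and 0.006325 for amacrine cells, 3.08e-06 and 0.01687 for ganglion cells, and 7.237e-07 and 8.738e-06 for oxidative phosphorylation. They were 0.0003088 and 0.002318 for the dendrite cytoskeleton and 0.004627 and 0.005185 for cone bipolar cells. Another split gave a lower p for cones (0.0002288 against 0.000316), glutamate receptors (0.004782 against 0.004983) and the lens list (1.648e-14 against 4.721e-06); for the lens 4 of 10 splits, the real one included, were as low.

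Pairs of neighbouring genes were also counted among the 100 genes of smallest p. There were 4 such pairs, against a mean of 0.769 in 10000 random sets of genes. A share of 0.0073 of these sets held as many. The count was prompted by Usp47 and Dkk3. Without them, 98 genes held 3 pairs against a mean of 0.74, and a share of 0.0386 of random sets held as many. Genes were drawn as if independent and the library labels were not permuted. These shares therefore do not test a difference between genotypes. The 4 pairs were Usp47 with Dkk3, Ehd4 with Pla2g4e, Eid1 with Secisbp2l, and Rasgrf1 with Ctsh. On chromosome 2 Pla2g4e (120166412 to 120245335) was at a log2 fold change of 0.99 and Ehd4 (120089175 to 120154606) at -0.60, each short of the threshold.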
